A study of Mus musculus with 4 samples.

How the data were processed

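RNA of Tregs from spleen and thymus of WT and deltaDC mice was labelled with Cy3 by a low-input kit and hybridised to 4 one-colour arrays of 1 mouse design, per the labels. The labels also give the pooling of cells of 3 mice per genotype, a negative-selection kit for splenic CD4 T cells, depletion of CD8-positive thymocytes, and the sort for DAPI-negative, CD4-positive, CD25-positive cells. Groups were taken from the sample labels: 1 array each of WT spleen, deltaDC spleen, WT thymus and deltaDC thymus.

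Per the file headers, the deposited scanner files hold fluorescence intensity read by Agilent Feature Extraction 10.7.3.1, which subtracts background and detrends signal within an array and does not scale between arrays, together with other columns of flags, 0 or 1. The authors also deposited a matrix whose header states background subtraction, quantile normalization and log2 values, with no tool named. Its columns hold 59303 spots and have medians of 4.10 (WT spleen), 4.11 (deltaDC spleen), 4.15 (WT thymus) and 4.10 (deltaDC thymus). Each matrix column had its highest Pearson r across genes, 0.997 in all 4 cases, with the scanner array of the same label, so direction follows from the scanner files, the log base rests on the header, and no column was centred on 0. The offset and any rescaling behind the quantile step stay unknown. The scanner intensities were used for all reported values, and the matrix as an alternative.

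Each array holds 62976 spots, of which 3671 are controls. The 59305 others carry 55681 probes, 399 of them spotted 10 times. Probes were named through their RefSeq accessions in a table of the GRCm38 annotation, used for names only, while the files' probe coordinates are on mm9. This named 27509 probes by accession and 3549 by current symbol, giving 22297 symbols, and left 24623 probes unnamed, of which 16194 are long non-coding RNA probes known by position. Spots with an outlier flag (110 on WT spleen, 131 on deltaDC spleen, 151 on WT thymus, 168 on deltaDC thymus) were removed, and 0 spots were saturated. Intensities were set to log2, each array's 75th percentile (340.0, 392, 406 and 417 in the same order) was subtracted, repeated spots were averaged, and the probe with the highest mean represented a gene. Of 22296 genes, 13491 were well above background on at least 2 arrays and 12286 on all 4. Median signals were 17.0, 18.8, 20.2 and 21.4.

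In the comparisons of 2 arrays, genes well above background on both were counted at a difference of at least 2-fold. A gene above background on 1 array got a bound, its bright signal against the higher of its own dim signal and the lowest well-above-background signal of the other array. Where its own dim signal was the higher, the bound is the plain ratio to that signal and no strict lower limit. No p-value can be had for 1 array against 1. The spread between repeated spots gave the error. On 20 simulations with this spot error alone, 16.6 unchanged genes of 12529 were counted as 2-fold, and 1.40%, 99.6%, 99.8% and 100% of genes changed by 0.5, 1.5, 2 and 3 log2 units were. These simulations hold no variation between animals or labellings.

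Genotype plus organ was fitted over the 4 arrays with limma 3.58.1 (R 4.3.3; lmFit and eBayes), leaving 1 residual degree of freedom, on genes well above background on at least 2 arrays, with Benjamini-Hochberg adjusted p-values and a two-sided moderated test. The prior had 1.80 degrees of freedom. On 5 simulations, 200 genes changed between genotypes were recovered at 0%, and 3000 genes changed between organs at 89.7%, 97.2% and 98.6% for 2, 4 and 6 log2 units, with 119.4 false calls per simulation. The difference of genotype effects between organs would use the last degree of freedom and was given as a value without a test.

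The groupings, the 37 gene lists, the rule for named genes, the tests of the comparisons and their alternatives were fixed before the data were examined. Some tests of explanations were chosen after results were seen, as stated with them. The lists held 643 entries, of which 634 were on the array, and 8 genes stood in more than 1 list. They were Treg identity, effector Treg, resting and central T cell, immature thymocyte, T cell receptor signal response, IL-2 and STAT5 response, TNF receptor family, type I interferon response, interferon-gamma and antigen presentation, proliferation, helper T cytokines, helper T transcription factors, homing and adhesion, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, heat shock and immediate early stress, unfolded protein response, apoptosis and p53, and TGF-beta response. Marker lists were those of all T cells, B cells, plasma cells, conventional and plasmacytoid dendritic cells, macrophages and monocytes, neutrophils, basophils and mast cells, NK cells, CD8 T cells, gamma-delta T with natural killer T and innate lymphoid cells, erythroid cells, platelets, thymic epithelium, stroma and endothelium, and Y-linked genes with Xist. A list's median over its members well above background on at least 2 arrays was set against 10000 random lists of the same size matched on mean expression in 20 bins. On simulated data, 6% of 100 unshifted lists of 20 genes fell outside the central 95%, and 100% of lists shifted by 0.5 log2 units fell above it. Genes of a list can be regulated together, which random lists are not.

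Named genes were, for each comparison of 2 arrays, the 12 highest and 12 lowest measured genes and the 5 largest bounds each way, up to 4 members of each list by size of difference, and all detected members of the core Treg list. Symbols of predicted genes and receptor segments were left out, and a few genes that the rule takes are not reported here. Members beyond 4 of a list, and the genes picked out of the 55 shared by both organs, were named after their values were seen. Counting genes and probes at least 2-fold higher or lower on 1 array than on each of the other 3 was also chosen after the values were seen.

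Alternatives were normexp background correction with an offset of 50, scaling by medians, quantile normalization, the median over a gene's probes, no filter on dim genes, a filter for all 4 arrays, the authors' matrix, a 1.5-fold threshold, a further requirement of 3 spot errors, and eBayes with a trend or a robust trend. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps. No deposited column of samples was left out, and unnamed probes were not used in the comparisons.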

Results

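Regulatory T cells (Tregs), CD4 T cells that restrain immune responses and are programmed by the transcription factor Foxp3, were profiled from spleen and thymus of male wild-type (WT) and deltaDC mice of the C57BL/6 strain. The labels do not spell out deltaDC, which in the field is a name for mice depleted of dendritic cells, and they name no targeted gene whose level could check the genotype. Each of the 4 groups (WT spleen, deltaDC spleen, WT thymus, deltaDC thymus) had 1 array, made from cells pooled from 3 mice and sorted as live CD4+CD25+ cells, not on Foxp3. There were no replicate arrays, so the error given is the one between repeated spots of a probe on an array. The number of arrays limits the precision of every value.

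Between 48.7% of spots on the WT spleen array and 50.7% on the deltaDC spleen array were well above background, with 50.2% on the WT thymus and 50.6% on the deltaDC thymus array. A gene was taken as measured in a comparison when it was well above background on both arrays, and a gene above background on 1 of them was given only a bound. Repeated spots differed by an SD of 0.31 log2 units at signals under 50 and of 0.05 above 10000. Foxp3 itself was bright on all 4 arrays, with signals of 10226 on WT spleen, 10992 on deltaDC spleen, 9283 on WT thymus and 11360 on deltaDC thymus. The Y-linked genes Ddx3y and Eif2s3y were measured on all 4 arrays and Xist, which silences the second X chromosome of females, on none.

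The first comparison asked how splenic Tregs of deltaDC mice differ from those of WT mice. Most genes of the effector Treg, cytokine and cell cycle lists were higher on the deltaDC spleen array, as were 7 of 9 detected natural killer (NK) cell markers. Of resting T cell genes 5 of 20 were lower, while most genes of the core Treg programme lay within 2-fold. Of 12529 genes measured on both arrays, 1053 (8.40%) differed at least 2-fold, 799 higher and 254 lower. Of these, 263 differed at least 4-fold. A further 301 genes had a bound of at least 2-fold higher and 258 of at least 2-fold lower.

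Of 30 effector Treg genes measured on both spleen arrays, 25 were at least 2-fold higher on the deltaDC array and 0 lower, and the list's median log2 difference was 2.07. Of the 29 above background on all 4 arrays, 15 were at least 2-fold higher on deltaDC spleen than on every other array, and 6 were at least 2-fold lower on WT spleen than on every other. Galectin-3 (Lgals3) had a log2 difference of 5.0, the granule protease Gzmb 3.78 and the chemokine receptor Ccr2 3.72. The terminal differentiation marker Klrg1 differed by 2.93 and Il10, a suppressive cytokine, by 2.15. Of 18 core Treg genes, 16 stayed within 2-fold. The exceptions were Gpr83 at -1.47 and Lrrc32, which holds latent TGF-beta on the Treg surface, at -1.07. Foxp3 differed by -0.10, with a spot error of 0.07, the IL-2 receptor chains Il2ra and Il2rb by -0.90 and 0.02, and Ctla4, Ikzf2 and Ikzf4 by -0.06, -0.02 and -0.39. The other core genes were Izumo1r at -0.67, Nt5e at -0.29, Swap70 at -0.23, Nrp1 at -0.18, Itgb8 at -0.06, Entpd1 at 0.01, Tnfrsf18 at 0.21, Socs2 at 0.29, Tnfrsf4 at 0.36 and Capg at 0.54. Of 20 genes of resting and central T cells, 5 were at least 2-fold lower: Igfbp4 at -2.22, Dapl1 at -2.01, Il6ra at -1.29, the survival factor Bcl2 at -1.20 and the quiescence factor Bach2 at -1.03. On WT spleen, 3 of the 20 were at least 2-fold higher than on every other array, and on deltaDC spleen 1 was that much lower.

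Of 11 helper T cytokine genes measured, 7 were at least 2-fold higher on the deltaDC spleen array, with a list median of 1.95, or 1.55 with dim values set to their bound. Il4 differed by 4.67, the chemokines Xcl1 and Ccl5 by 3.99 and 3.98, and Csf2 by 3.81. Among helper T transcription factors 6 were higher and 0 lower (median 0.69), led by Zbtb16, the factor of innate-like T cells, at 3.69, Id2 at 3.54 and the type 1 factor Tbx21 at 3.15. Of 20 homing genes 8 were higher and 1 lower (median 0.57), with Cxcr6 at 4.69, Cx3cr1 at 4.16 and Itga6 at -1.16. Of 31 proliferation genes 19 were at least 2-fold higher and 0 lower, with a median of 1.21, and all 19 were at least 2-fold lower on the WT spleen array than on each of the other 3 arrays. Nusap1 differed by 2.30, Ube2c by 2.28, Ccnb2 by 2.25 and Ccna2 by 2.20.

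Markers of other lymphoid and myeloid cells moved on the same pair of arrays. The NK cell list had a median of 2.06, with the receptors Klrb1c at 4.90 and Klrd1 at 4.19 and the granule protein Nkg7 at 3.19. The list of gamma-delta T, natural killer T and innate lymphoid cells had a median of 2.62 and 5 of its members at least 2-fold higher. Among them were Cd163l1 at 5.38, the interleukin-1 receptor Il1r1 at 3.72, Zbtb16 at 3.69 and Il23r at 2.62. Neutrophil genes had a median of 4.65, with 2 members measured as higher and 5 by a bound. The granule proteins S100a9 and S100a8 were at least 373-fold and 85.7-fold higher, from dim signals on the WT array. This neutrophil median was -0.01 over the 3 members above background on all 4 arrays, a filter that drops members dim on WT spleen, S100a8 and S100a9 among them. The macrophage list had a median of 0.66, the erythroid list 1.30 and the conventional dendritic cell list 1.48, or 0.70 with dim values at their bound. B cell genes had a median of 0.22, plasma cell genes 1.05, plasmacytoid dendritic cell genes 0.15, basophil and mast cell genes 0.16, CD8 T cell genes 0.23, platelet genes -0.41, thymic epithelial genes 0.25, stromal genes -0.19, Y-linked genes -0.21 and genes of all T cells 0.02. The median of immature thymocyte genes was 0.03. With dim values set to their bound, these medians were 1.99 for NK cells, 0.01 for B cells, 0.62 for plasma cells, -0.0023 for plasmacytoid dendritic cells, 0.23 for basophils and mast cells, 0.36 for CD8 T cells, 0.0078 for thymic epithelium and -0.0014 for stroma.

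Among response programmes, the interferon-gamma and antigen presentation list had a median of 0.20 and 5 of 19 members at least 2-fold higher. These were the MHC class II genes H2-Aa at 3.01, H2-Eb1 at 2.49 and H2-Ab1 at 2.40, their chaperone Cd74 at 2.15 and the chemokine Cxcl10 at 1.69. The first 4 were at least 2-fold lower on the WT spleen array than on each other array. With the median over a gene's probes this list's median was -0.01. Of 22 heat shock and immediate early genes, 4 were at least 2-fold lower, Fos at -1.76, Hspa1a at -1.49, Jun at -1.22 and Ppp1r15a at -1.19, while Gadd45b was higher at 1.09 and Ier3 by a bound of 3.21-fold (list median -0.20). TGF-beta response genes had a median of -0.27, with Id1 at -1.33, Smad7 at -1.07 and Tgfb3 at 2.96. Ribosomal protein genes had a median of -0.27, glycolysis genes 0.26, unfolded protein response genes 0.22 and oxidative phosphorylation genes 0.14. The lists of T cell receptor signal (0.03), IL-2 and STAT5 response (0.09), TNF receptor family (0.11), type I interferon response (-0.03), cholesterol synthesis (-0.05) and apoptosis and p53 (0.15) had medians inside the central 95% of random lists. Within these, Il18rap stood at 3.63, Il18r1 at 2.16, Tnfsf14 at 2.37 and Fasl at 2.08. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 3.09 by its brightest probe and at -1.79 by the median over its probes.

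The genes measured as highest on the deltaDC spleen array relative to WT were Klrc1, an NK receptor chain, at 63.1-fold, Ifitm1, an interferon-induced membrane protein, at 47.6-fold, Cd163l1 at 41.6-fold, Lgals3 at 32.1-fold, Klrb1c at 29.8-fold and Klrb1a at 28.7-fold. Lilr4b (28.3-fold), Il17re (27.9-fold), Cxcr6 (25.8-fold), Il4 (25.5-fold), the antimicrobial peptide gene Camp (25.2-fold) and Ltb4r1 (21.7-fold) followed. The lowest were Cyp4f18, a leukotriene-metabolising enzyme, which was 74.3-fold lower, and Gbp2b, an interferon-induced GTPase, which was 15.7-fold lower. Kcnh6 (12.5-fold), Arntl2 (5.0-fold), Stra6 (4.93-fold), Cyp2d34 (4.81-fold), Shc4 (4.68-fold), Igfbp4 (4.64-fold), Wfdc2 (4.62-fold), Lzts3 (4.38-fold), Cabp5 (4.27-fold) and Gas1 (4.24-fold) were also lower. Of these 12 lower genes, 9 were at least 2-fold higher on the WT spleen array than on each of the other 3 arrays. Of the 12 higher genes, 3 (Ifitm1, Cd163l1 and Lgals3) were at least 2-fold lower on it than on each of the others. Over the 12286 genes above background on all 4 arrays, 66 were that much higher and 290 that much lower on WT spleen than on every other array, and 301 and 56 on deltaDC spleen. Another probe of Shc4 gave a log2 difference of -0.75, and the median over the probes of Gas1 gave 0.89. By bound, Mpo (30.9-fold) and Ltf (28.1-fold) were higher, and Kcnd3 (17-fold), Dpf3 (13.5-fold) and Vmn1r66 (12.5-fold) lower, each at least by that fold. The bounds of Sulf2 (29.2-fold higher), Rhox2h (21.6-fold lower) and Cyp26b1 (20.7-fold lower) are plain ratios to a dim signal and no strict lower limits. Spot errors of these named genes ranged from 0.05 to 0.34 log2 units. With normexp background correction the count of genes at least 2-fold different was 568, and without the filter on dim genes 3095. No test of this difference was possible with 1 array per group, and 15 of 37 list medians lay above and 4 below the central 95% of random lists matched on expression.

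The second comparison asked the same of thymic Tregs. The genotypes differed less there in number of genes: 6 of 10 B cell, 5 of 9 neutrophil and 2 of 6 erythroid genes were at least 2-fold higher on the deltaDC thymus array, 7 of 22 stress and immediate early genes were lower, and effector Treg genes were within 2-fold. Of 13039 genes measured on both thymus arrays, 208 (1.60%) differed at least 2-fold, 121 higher and 87 lower, and 21 differed at least 4-fold. Bounds of at least 2-fold covered a further 165 higher and 87 lower genes.

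Of 18 core Treg genes, all measured on both thymus arrays, 0 differed at least 2-fold. Foxp3 differed by 0.25, Il2ra by -0.14, Ctla4 by 0.01, Ikzf2 by -0.10, Entpd1, an ectoenzyme that degrades ATP, by -0.81 and Nrp1 by -0.70. The medians of the effector Treg list (0.0016), the core Treg list (-0.0020), the helper T transcription factors (0.0083) and the homing genes (0.0029) were near 0, and Klrg1 had the largest effector difference at 0.97. Of 12 cytokine genes measured, Il4 was higher at 1.02 and Ifng, the type 1 cytokine, lower at -1.42 (list median -0.02). Proliferation genes had a median of -0.16, with Kif11, a mitotic motor, at -1.0. Type I interferon response genes had a median of 0.16, with Oasl1 at 0.75 and Ifit1 at 0.65, and 0 of 30 reached 2-fold. Of 22 heat shock and immediate early genes, 6 were at least 2-fold lower by measurement and 1 by bound, and 0 were higher (list median -0.22). Hspa1a, which encodes an inducible heat shock protein, differed by -2.66, Fos by -1.90, Ppp1r15a by -1.52 and Jun by -1.16.

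B cell genes had a median of 1.52 in the thymus, and 6 of 10 were at least 2-fold higher on the deltaDC array. Vpreb3, a surrogate light chain gene of B cell precursors, differed by 3.25, Fcrla by 1.84 and Cd79a by 1.64. Neutrophil genes had a median of 1.01 and 5 members higher, with S100a8 at 2.85 and S100a9 at 2.79. That median was -0.02 over the 3 members above background on all 4 arrays, which leaves out S100a8 and S100a9, dim on WT spleen. The erythroid list had a median of 0.61, with the haem synthesis enzyme Alas2 at 2.63 and Hba-a1 at 2.0. NK cell genes had a median of 0.77, CD8 T cell genes 0.62, genes of gamma-delta T, natural killer T and innate lymphoid cells 0.46, thymic epithelial genes 0.70 and macrophage genes 0.31, the last 0.10 with dim values at their bound. Of 9 conventional dendritic cell genes, 2 were lower, the chemokine Ccl17 at -1.93 and the costimulatory ligand Cd86 at -1.02, while Itgax, which encodes CD11c, differed by -0.29 (median -0.06). Of 8 plasmacytoid dendritic cell genes, Cox6a2 was higher at 5.95 and Tcf4, the lineage factor, lower at -1.29 (median -0.06). Oxidative phosphorylation genes had a median of 0.25, ribosomal protein genes 0.19 and T cell receptor signal genes 0.04.

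Cox6a2, a subunit of cytochrome oxidase, was the gene with the largest measured thymic difference, 62.0-fold higher on the deltaDC array. Vpreb3 was 9.50-fold higher, S100a8 7.21-fold, S100a9 6.92-fold, Lamb1 6.53-fold, Pkhd1 6.39-fold, Alas2 6.20-fold and the beta-globin genes Hbb-bs, Hbb-b2 and Hbb-bt 5.55-fold, 4.45-fold and 4.30-fold. Mdfi was 4.99-fold and Anp32a 5.16-fold higher, although another probe of Anp32a gave a log2 difference of -0.17. On the other side, Snai2 was 7.46-fold lower, Cyp4f18 6.65-fold, Hspa1a 6.34-fold, Stfa3 6.10-fold, the lectin Cd209d 5.89-fold, Proc 5.36-fold, Bbs7 5.03-fold, Ccl17 3.82-fold, Fos 3.74-fold, Pou4f1 3.58-fold, Upb1 3.42-fold and H2ac6 3.36-fold. Another probe of Bbs7 gave 0.32. By bound, Ptprb (10.6-fold), Defa36 (9.80-fold), Myh13 (8.90-fold), Bpifb2 (8.86-fold) and Olfr340 (7.83-fold) were at least that much higher, and Pik3c2g (9.03-fold), Gpc6 (8.20-fold), the dendritic cell lectin Cd209a (7.57-fold) and Gbp2b (7.48-fold) at least that much lower. Spot errors of these genes ranged from 0.03 to 0.34 log2 units. With normexp the count was 58, without the filter 1655 and with genes above background on all 4 arrays 136 (66 higher and 70 lower). This difference was not tested either, and 10 of 37 list medians lay above and 3 below the central 95% of random lists.

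Set against each other over 12286 genes above background on all 4 arrays, the genotype differences of the organs had a Pearson r of 0.162 and a Spearman rho of 0.162 across genes, which are not independent replicates. At least 2-fold higher in both organs were 36 genes, where 4.12 would be shared if the organs were unrelated, and 19 were lower in both, where 1.32 would be. Lower in both were Cyp4f18, the stress genes Hspa1a, Fos, Jun and Ppp1r15a, and Cd86. Higher in both were Il1r1, Il4, Klrb1a, Klrb1c, Ifitm1, Camp, Alas2 and the globin genes Hba-a1 and Hbb-bt. Another 10 genes differed at least 2-fold in opposite directions, of which 8 were higher in spleen and lower in thymus. Among the 12286 genes, 767 were at least 2-fold higher and 232 lower in spleen, and 66 and 70 in thymus. The expected counts treat the calls of the organs as independent, and none was computed for opposite genes. How the excess of shared genes compares with that of opposite genes was therefore not assessed. With normexp 13 genes were shared and 2 opposite, and without the filter 342 and 210. The arrays of the comparisons are separate, but the spleen and thymus cells of a genotype came from the same 3 mice.

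**Figure D1:**
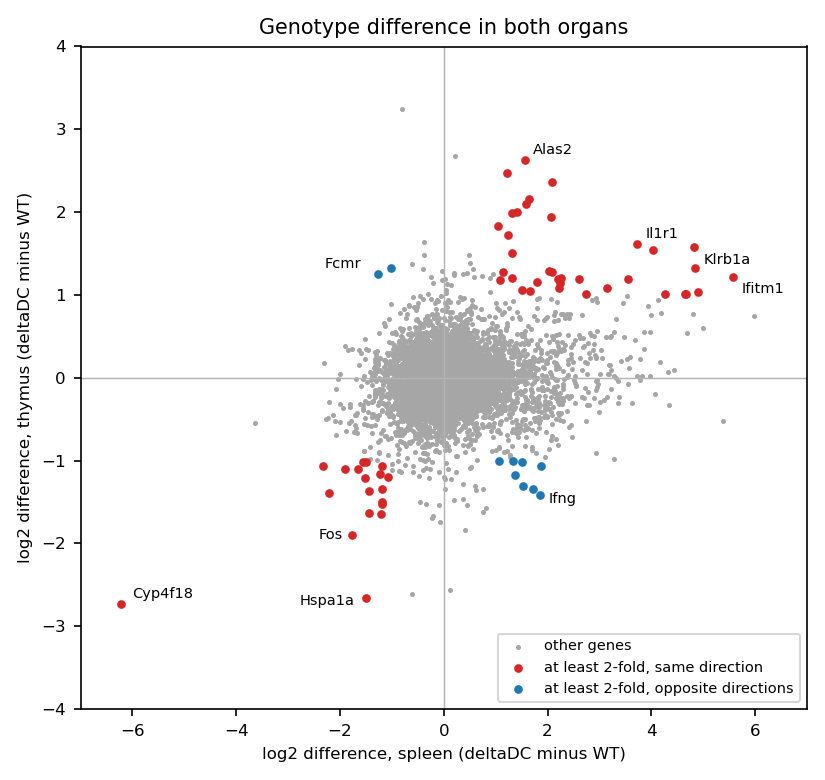
Each point is a gene above background on all 4 arrays, with its log2 difference (deltaDC minus WT) in spleen on the horizontal axis and in thymus on the vertical axis, 1 array per group. Red points are the 55 genes at least 2-fold different in the same direction in both organs, among them Cyp4f18 at -6.22 and -2.73, and blue points the 10 in opposite directions.

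A model of genotype plus organ over the 4 arrays, with 1 residual degree of freedom, was the only test of genotype that the design allowed. Its residual holds array error and any difference of the genotype effect between organs. Both organs of a genotype came from the same pool of 3 mice. The residual therefore leaves out any spread between mice that both organs share, and its p-values do not extend to other mice. With limma, 0 of 13491 genes passed an adjusted p of 0.05 for genotype, the smallest adjusted p was 0.807, and 578 genes had an unadjusted p under 0.05. Adjusted over the list alone, 3 heat shock and immediate early genes, 3 erythroid genes, 2 B cell genes and 1 NK cell gene passed for genotype, beside 0 in each of these lists over all genes tested, and 0 genes passed in every other list either way. On simulated data with 200 genes changed between genotypes, this fit recovered 0% of changes of 1, 2 or 3 log2 units, so its count of 0 does not exclude 200 such genes. With 3000 genes changed between organs by a mix of 2, 4 and 6 log2 units, it recovered 89.7% of those changed by 2.

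The third comparison asked how Tregs of thymus and spleen differ in WT mice. Most genes of the cell cycle were higher in the WT thymus, as were 9 of 19 genes of immature thymocytes and 5 of 23 of T cell receptor signalling, and 5 of 20 genes of resting T cells were lower. The cells were sorted on CD4 and CD25, not on Foxp3. Whether the immature thymocyte genes came from Tregs or from other sorted cells was not tested, here or in deltaDC mice. Of 12482 genes measured on both arrays, 1193 (9.56%) differed at least 2-fold, 816 higher in thymus and 377 lower, with bounds for a further 427 and 144.

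Of 19 immature thymocyte genes, 5 were measured as at least 2-fold higher and 4 by bound, and the list median was 0.77. Rag1, which cuts receptor genes for rearrangement, differed by 7.19, Dntt, which adds bases at the junctions, by 7.07 and Cd24a by 5.26. Of 23 T cell receptor signal genes 5 were higher and 0 lower (median 0.35): the nuclear receptors Nr4a2 at 2.47, Nr4a3 at 2.34 and Nr4a1 at 1.16, the phosphatase Dusp4 at 2.41 and Itm2a at 1.78. Of 31 proliferation genes 24 were higher and 0 lower (median 1.58), with Top2a, a topoisomerase of dividing cells, at 2.89 and Nusap1 at 2.75. This shares the WT spleen array with the genotype comparison in spleen, and 19 of the 31 were at least 2-fold lower on it than on each other array. Of 30 effector Treg genes measured, 7 were higher and 1 lower (median 0.37), with Ccr8 at 2.86, Fgl2 at 1.66 and Ccr6 and Itgae at 1.64. These named genes were among the 6 effector genes at least 2-fold lower on WT spleen than on each other array. Of 20 resting T cell genes 5 were lower and 0 higher (median -0.53): Dapl1 at -2.84, Il6ra at -1.57, Klf3 at -1.36, Klf2 at -1.17 and Igfbp4 at -1.05. On the WT spleen array, which the genotype comparison in spleen also uses, 3 of the 20 were at least 2-fold higher than on each other array. Cholesterol synthesis genes had a median of -0.60, with 2 of 18 at least 2-fold lower (Insig1 at -1.41), and ribosomal protein genes -0.53, with 0 of 28. Of the core Treg genes, Izumo1r at -1.12 and Socs2 at -1.11 were lower and 16 were within 2-fold. Foxp3 differed by -0.40.

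Other programmes moved both ways in WT thymus. Type I interferon response genes had a median of 0.18, with Ifi44 at 1.93 and Mx2 at 1.48. The interferon-gamma and antigen presentation list had a median of -0.42 while H2-Aa stood at 2.59, H2-Ab1 at 2.56, H2-Eb1 at 2.32 and Cd74 at 1.72, the same 4 genes low on WT spleen alone, against Gbp3 at -1.44. TGF-beta response genes had a median of 0.44, with Ldlrad4 at 1.37 and Pmepa1 at 1.26. The heat shock and immediate early list had a median of 0.20, with Hspa1a at 5.79. The IL-2 and STAT5 list had a median of 0.03, with the granzyme Gzma at 3.82, Socs3 at -2.01 and Pim1 at -1.34. Cytokine genes had a median of 0.68, with Xcl1 at 3.21, Ccl4 at 2.29 and Csf1 at -1.70, and homing genes -0.37, with Cx3cr1 at 3.28. Of these, Gzma, Xcl1, Ccl4 and Cx3cr1 were also at least 2-fold lower on WT spleen than on each other array. Lists of cells outside the T lineage had medians on both sides of 0. B cell genes had a median of 2.07, conventional dendritic cell genes 2.13, plasmacytoid dendritic cell genes 1.22, plasma cell genes 2.93, mast cell and basophil genes 2.01, NK cell genes 0.81, thymic epithelial genes 1.19 and stromal genes 1.90. Macrophage genes had a median of -0.49, with Hmox1, a haem-degrading enzyme, at -2.43, and platelet genes -1.99. With dim values at their bound, the medians were 1.41 for B cells, 1.43 for conventional dendritic cells, 1.58 for stroma and -1.17 for platelets. The conventional dendritic cell median was -0.15 over the genes above background on all 4 arrays. The basophil and mast cell median was -0.02 over those genes and -0.13 with dim genes kept, and the NK cell median was -0.05 with dim genes kept.

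The largest measured differences in WT mice were Rag1 at 146-fold and Dntt at 135-fold higher in thymus, then Myl10 (65.5-fold), Evpl (62.3-fold), Hspa1a (55.3-fold), Wdfy4 (43.5-fold), Ly6d (40.1-fold), Aqp11 (39.0-fold), Cd24a (38.3-fold), Cd163l1 (37.3-fold), Pomgnt2 (30.3-fold) and Adgrg1 (30.2-fold). Lower in thymus were Lingo4 (11.5-fold), Tmem273 (11.2-fold), Rflnb (10.2-fold), Serpina9 (9.84-fold), the Notch regulator Dtx1 (8.77-fold), Dapl1 (7.14-fold), Osgin1 (6.98-fold), Sorcs2 (6.89-fold), Cyp4f18 (6.38-fold), Art2b (6.33-fold), Pde2a (5.41-fold) and Hmox1 (5.37-fold), whose other probe gave a log2 difference of -1.09. Evpl, Wdfy4 and Cd163l1 were at least 2-fold lower on WT spleen than on each other array. Dapl1, Osgin1, Sorcs2 and Cyp4f18 were at least 2-fold higher on it than on each other array. By bound, Tff1 (236-fold), Rab44 (225-fold), Ptcra (207-fold), which encodes the pre-T cell receptor alpha chain, and Notch3 (134-fold) were at least that much higher. The macrophage protein gene Cd5l (15.2-fold), Grm6 (14.4-fold) and Cntn1 (11.1-fold) were at least that much lower. The bounds of Epb41l4b (203-fold higher), Rhox2h (16.2-fold lower) and Cyp26b1 (14.7-fold lower) are plain ratios to a dim signal and no strict lower limits. With normexp the count of genes was 704, and without the filter 3308. Of the 37 list medians, 16 lay above and 7 below the central 95% of random lists.

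The fourth comparison asked the same organ question in deltaDC mice. Some immature thymocyte genes (9 of 19) and T cell receptor signal genes (6 of 23) were again higher in thymus, while most effector Treg genes, 6 of 12 cytokine genes and 10 of 20 homing genes were lower there. Of 12803 genes measured on both arrays, 1474 (11.5%) differed at least 2-fold, 691 higher in thymus and 783 lower, with bounds for a further 595 and 211.

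Of 31 effector Treg genes measured, 18 were lower in deltaDC thymus than in deltaDC spleen and 1 was higher (median -1.27), with Gzmb at -3.50, Cxcr3 at -3.49, S100a6 at -3.43 and Ccr2 at -3.28. This shares the deltaDC spleen array with the genotype comparison in spleen. Of 29 effector genes above background on all 4 arrays, 15 were at least 2-fold higher on deltaDC spleen than on each other array. On deltaDC thymus, 0 were that much lower than on each other array. Likewise 4 of 11 cytokine, 4 of 20 homing and 4 of 16 helper T transcription factor genes were that much higher on deltaDC spleen. Cytokine genes had a median of -1.03, with 6 of 12 lower, led by Il4 at -5.15 and Ifng at -4.28. Homing genes had a median of -1.02, with 10 of 20 lower, led by Cxcr6 at -4.35, and helper T transcription factors -0.60, with Zbtb16 at -4.09, Tbx21 at -4.05 and Id2 at -3.08. Immature thymocyte genes had a median of 0.81, with Dntt at 7.35 and Cd24a at 4.85, and T cell receptor signal genes 0.33, with Dusp4 at 2.82, Nr4a3 at 2.31, Itm2a at 2.08 and Nr4a1 at 1.69. Of 31 proliferation genes, 0 differed at least 2-fold (median 0.16). Of 30 type I interferon response genes 7 were higher and 0 lower (median 0.55), with Ifi44 at 2.56 and Mx2 at 2.07. TGF-beta response genes had a median of 0.94, resting T cell genes 0.22, TNF receptor family genes -0.48, cholesterol synthesis genes -0.52, interferon-gamma and antigen presentation genes -0.34 and unfolded protein response genes -0.34. Among core Treg genes, Gpr83 was higher at 1.22, Entpd1 lower at -1.81 and Socs2 lower at -1.63, with Foxp3 at -0.04.

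B cell genes had a median of 2.94 in this comparison, plasma cell genes 1.63, mast cell and basophil genes 1.41, thymic epithelial genes 2.0, stromal genes 2.10, erythroid genes 0.62 and plasmacytoid dendritic cell genes 0.45. Neutrophil genes had a median of -2.71, NK cell genes -0.75, genes of gamma-delta T, natural killer T and innate lymphoid cells -2.10, macrophage genes -1.03, platelet genes -1.03 and conventional dendritic cell genes -0.42. With dim values at their bound, the macrophage median was -0.77 and the platelet median -0.39. Dntt was 164-fold higher in deltaDC thymus, Cox6a2 85.6-fold, Epb41l4b 72.1-fold, Ly6d 61.9-fold, Tmem121 51.4-fold, Myl10 46.3-fold, Tff1 42.5-fold, Rab44 39.6-fold, Aqp11 38.8-fold, Ms4a1 37.0-fold and Adgrg1 31.5-fold. Tmem273 was 65.4-fold lower, Il4 35.6-fold, Klrc1 35.0-fold, Klrb1c 25.0-fold, Tmprss13 22.6-fold, Arl4d 22.2-fold, Adam8 21.4-fold, Cxcr6 20.5-fold, Cd5l 19.7-fold, Ifng 19.5-fold, Klrb1a 19.2-fold and Soat2 18.0-fold. By bound, Ptcra (317-fold), Rag1 (257-fold), the imprinted gene H19 (244-fold) and Notch3 (177-fold) were at least that much higher. Trpm6 (29.7-fold), the protease Mmp9 (25.2-fold), Klrc3 (13.1-fold), Tafa3 (11.6-fold) and Fcna (11.5-fold) were at least that much lower. The bound of Endou (177-fold higher) is the plain ratio to a dim signal and no strict lower limit. With normexp 950 genes were counted, and without the filter 3560 (1924 higher and 1636 lower). Of the 37 list medians, 13 lay above and 13 below the central 95% of random lists.

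**Figure D2:**
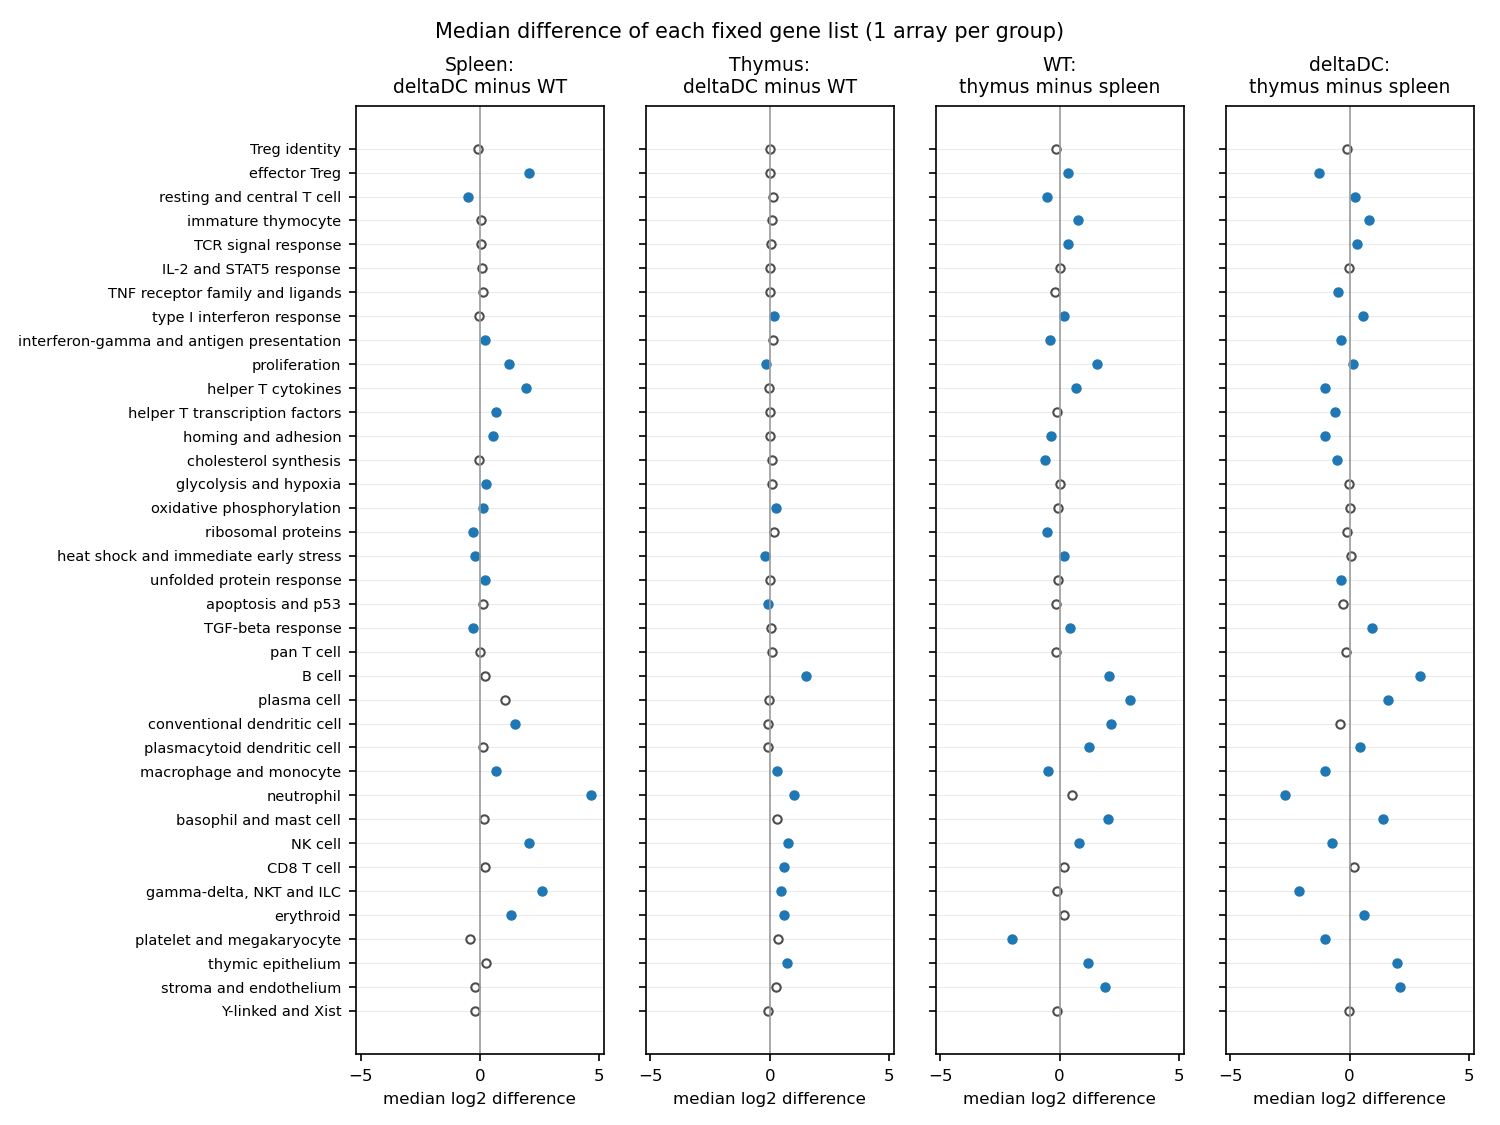
Median log2 difference of each of the 37 gene lists (horizontal axes) in the 4 comparisons, 1 array per group, with filled points for medians outside the central 95% of 10000 random lists matched on expression and open points for the rest. The effector Treg list stands at 2.07 in the spleen genotype comparison and at 0.0016 in the thymus.

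Over the 12286 genes above background on all 4 arrays, the organ differences of WT and deltaDC mice had a Pearson r of 0.576 and a Spearman rho of 0.553 across genes. Higher in thymus in both genotypes were 345 genes, where 37.6 would be shared by unrelated differences, and 166 were lower in both, where 20.9 would be, while 24 went opposite ways. With normexp 301 were shared, and without the filter 1254. In the model of genotype plus organ, limma called 0 of 13491 genes for organ, with a smallest adjusted p of 0.0506 and 2697 genes at an unadjusted p under 0.05. It called 126 with a trend in the prior variance, 117 with a robust trend, 279 with normexp and 55 with the median over a gene's probes. Adjusted over the list alone, 9 immature thymocyte, 5 T cell receptor signal, 7 B cell, 7 macrophage, 5 thymic epithelial and 5 stromal genes passed for organ, beside 0 in each over all genes tested. In the same way 4 heat shock and immediate early, 3 TGF-beta response, 3 plasmacytoid dendritic cell and 3 CD8 T cell genes passed, and 2 each of the IL-2 and STAT5, cytokine, homing, plasma cell, conventional dendritic cell, erythroid and platelet lists. The glycolysis, basophil and mast cell, and NK cell lists had 1 each, again beside 0 over all genes.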

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

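The tests of a lower T cell share, with and without the neutrophil and NK cell lists, of Foxp3, of T cell receptor signal and of other probes were chosen after the result was seen. Those of a second NK cell set, a second stress set and chromosome windows were set down beforehand.

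Most effector Treg and innate lymphocyte genes were higher on the deltaDC spleen array, and the design offers the genotype as a biological explanation, which stays open as untested. A lower share of sorted T cells would raise every other cell type alike. The B cell (0.22), platelet (-0.41) and macrophage (0.66) medians spread over 1.07 log2 units, between the bounds set for and against it. The platelet median lay below 0, against that forecast, but rests on 4 detected genes. With dim genes kept, B cell genes had the lowest of the 5 cell type medians at 0.21, so the platelet median was then above 0. The spread was wider with the NK cell list (2.47), whose genes are part of the pattern, and the neutrophil list (5.07). With dim values at their bound, the neutrophil median was 4.65 and the B cell median 0.01, which also goes against an equal rise. Only 4 of 9 neutrophil and 5 of 10 B cell genes were measured on both spleen arrays, so this explanation stays open. NK cells in the sort are a candidate source that the CD4 kit and the CD4 and CD25 gate would remove: of a second set of 12 NK cell genes 7 were detected, with a median of 1.41 and members both higher (Klra7 at 3.93) and lower (Klra1 at -1.41), so it cannot be told apart from NK receptors expressed by T cells. A larger share of CD4+CD25+ cells without Foxp3 also stays open, since Foxp3 differed by -0.10 with a spot error of 0.07, under 2 spot errors either way. Neutrophil RNA, whose source the same kit and gate would remove, reached signals of 6529 for S100a9 and 1499 for S100a8 on the deltaDC spleen array against 3.39 and 3.64 on WT, and its cause was not tested.

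Of 22 stress and immediate early genes, 4 were at least 2-fold lower on both deltaDC arrays: Fos (-1.76 in spleen and -1.90 in thymus), Hspa1a (-1.49 and -2.66), Jun (-1.22 and -1.16) and Ppp1r15a (-1.19 and -1.52). Weaker T cell receptor signal would lower its response genes too, but it stays open: their list medians were 0.034 in spleen and 0.035 in thymus, with 11 members below 0 and 12 above in each, which decides nothing. More handling stress of the WT cells is a candidate explanation that also stays open: a second set of 15 genes induced by tissue dissociation had medians of 0.11 in spleen and -0.13 in thymus, the lower of which lies between the bounds set for and against it. Handling and genotype cannot be told apart with 1 pool each, and a biological effect of genotype was not tested.

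Of the genes at least 2-fold different in both organs, 36 were higher and 19 lower. Passenger DNA of another strain around a transgene, as the source of the set, would gather it in 1 chromosome region. The fullest 20 Mb window, on chromosome 7, held 3 of 51 gene families (Syce1, Ifitm1 and Tspan4). In 10000 random draws the median was 4, with this count at percentile 20.8. These values argue against passenger DNA for the set as a whole, but a window count cannot decide for single genes. Signal of a single probe may account for some: of 7 genes with another measured probe, 2 (Rgs9 and Anp32a) had it under 2-fold in both organs, too few genes to decide for the rest. Cyp4f18 kept its direction on its other probe, at -5.85 in spleen and -1.97 in thymus. As the organs share the same mice, a trait of these pools also stays open and was not tested.

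A set of 10 genes differed at least 2-fold in opposite directions in spleen and thymus, each organ having 1 array per genotype, and the difference between organs was not tested. As the thymic minus the splenic log2 difference, Ifng stood at -3.28, Serinc2 at -3.05, Ccdc80 at -2.94, Shtn1 at -2.83, Ildr1 at -2.54, Ccn4 at -2.51, Kif11 at -2.34 and Gpr15 at -2.06. Ube2d1 stood at 2.35 and Fcmr at 2.51.

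Probes without a gene name, which no comparison used, also differed at least 2-fold. There were 689 of 8235 in the spleen genotype comparison (133 higher and 556 lower), 175 of 8182 in the thymus (67 and 108), 932 of 8037 between organs in WT mice (211 and 721) and 688 of 8084 between organs in deltaDC mice (315 and 373).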

How the results depend on the processing

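Counts of genes at least 2-fold different stayed within 1.5 times the reported count under median scaling, quantile normalization, the median over a gene's probes, the 3 spot error requirement and the authors' matrix (spleen 1020 to 1084, thymus 199 to 259, WT organ 1178 to 1291, deltaDC organ 1450 to 1552). With normexp they were 568 (spleen), 58 (thymus), 704 (WT organ) and 950 (deltaDC organ). The offset of 50 in that setting shrinks folds at low signals, and how much of the drop it accounts for was not tested. Without the filter on dim genes, which adds genes near background, they were 3095, 1655, 3308 and 3560, and at 1.5-fold, a looser threshold, 2307, 772, 2887 and 3040. Asking for all 4 arrays left 136 in the thymus, since fewer genes enter. The higher against lower split was 121 to 87 in the thymus, but 386 to 386 at 1.5-fold and 66 to 70 with all 4 arrays. Between deltaDC organs it was 691 to 783, but 603 to 915 with median scaling and 1924 to 1636 without the filter. Between WT organs it was 816 to 377, but 1444 to 1443 at 1.5-fold, and in spleen 799 to 254, but 1728 to 1367 without the filter and 483 to 85 with normexp. Genes shared by both organs numbered 13 with normexp and 342 without the filter, beside 55, and those shared by both genotypes 301 and 1254, beside 511. Opposite genes numbered 2 with normexp, 16 with the probe median and 210 without the filter, beside 10. The genotype effect had 0 calls under every alternative, with smallest adjusted p-values from 0.764 to 0.854. The organ effect had 279 calls with normexp, 55 with the probe median, 126 with a trend and 117 with a robust trend, and 0 under the others, with smallest adjusted p-values from 0.00779 to 0.0835. The cause was not tested.

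Of 1028 list medians under alternatives, 965 stayed inside or outside the central 95% as reported, 36 came inside it, 19 left it and 8 reversed. Between 72 and 81 of the medians lay outside it. Reversals were counted only for medians reported outside the central 95%. Changes of sign within it were not counted, such as the B cell median in spleen, 0.22 as reported and -0.09 with all 4 arrays. With the probe median, the interferon-gamma list in spleen was -0.0084 and the apoptosis list in thymus 0.0019. With all 4 arrays, the neutrophil medians were -0.014 in spleen and -0.020 in thymus, and the organ medians in WT mice -0.15 for conventional dendritic cells and -0.021 for basophils and mast cells, since dim members drop out. The spread of the 5 cell type medians in spleen, 5.07, was 2.35 there, from B to NK cells and with no platelet value, and 3.15 to 5.07 under the other settings. Without the filter, the basophil and mast cell median was -0.13 and that of NK cells -0.048. Of 2385 gene values, 2381 kept their direction. The exceptions, all with the probe median, were Cdkn1a at -1.79 in spleen and -1.78 between WT organs, Gas1 at 0.89 in spleen and Gzmk at -1.25 between deltaDC organs, as probes of a gene differ. The organ effect, fitted beside genotype, pairs the organs of the same mice, while no mice link the genotypes. Leaving out an array ends 2 of the 4 comparisons, leaves the other 2 as they are and leaves the model no residual degree of freedom. Signals near background limit the bounds, and 7752 genes were above it on no array.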

Other observations

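Receptor segments, described as groups, were read beside the marker lists. Immunoglobulin segments measured on both arrays had a median log2 difference of -0.04 between genotypes in spleen (6 genes) and 0.40 in thymus (7 genes), and between organs of 1.12 in WT and 2.0 in deltaDC mice (6 genes each). T cell receptor segments, 12 measured, had medians of 0.10, 0.13, -0.22 and -0.04 in the same order.

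Hba-a1 and the haem enzyme gene Alas2 were higher on both deltaDC arrays. Hba-a1 had signals of 1111 in WT and 3427 in deltaDC spleen and of 2939 in WT and 12118 in deltaDC thymus, and Alas2 followed at 35.4 and 121 in spleen and 42.3 and 269 in thymus. The globin genes are close paralogues, so their probes are not independent. Thymic dendritic cell genes did not move together: Itgax had signals of 222 in WT and 187 in deltaDC thymus, and Ccl17 of 88.2 and 23.7. Unnamed probes leaned the other way from named genes in spleen, with 556 of 689 lower on the deltaDC array, where 799 of 1053 named genes were higher, and between WT organs, with 721 of 932 lower in thymus, where 816 of 1193 named genes were higher. Both comparisons use the WT spleen array. Of 7560 unnamed probes above background on all 4 arrays, 173 were at least 2-fold higher on WT spleen than on each other array, beside 39 on deltaDC spleen, 10 on WT thymus and 13 on deltaDC thymus, and the cause was not tested.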
